A study of Mus musculus with 9 samples.

How the data were processed

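RNA-seq was measured in 9 libraries of KIT-positive, CD45-negative cells sorted from the dermis of female C57BL/6 mice. KIT is a receptor carried by cells of the melanocyte lineage, and CD45 marks immune cells. The groups were melanoblasts, the melanocyte precursors of newborn skin, at postnatal day 0.5 (n = 3), adult quiescent melanocyte stem cells (McSC) at 8 to 10 weeks (n = 4) and aged quiescent McSC at 24 months (n = 2). The adult and aged cells came from skin in telogen, the resting phase of the hair cycle. Per the labels' protocols, cells of several animals were pooled for each library, so p-values measure the spread between pools. The newborn and adult mice were bred in house from C57BL/6J, whereas the 24-month mice came from another colony at 21 months of age, so colony and age cannot be separated in the aged group. Group and replicate number were taken from the sample titles.

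Per the labels' protocols, 20 ng of total RNA with an RNA integrity number above 8.5 was amplified to cDNA with the Ovation RNA-Seq System V2. Libraries were made from 1000 ng of cDNA with the TruSeq RNA kit and 10 PCR cycles, and were sequenced together as 126-base read pairs on an Illumina HiSeq, with the same minimum depth stated for each. Amplification of a small input can change the balance of transcripts and gives no molecule counts. Per the submitters' processing notes, the authors used Trimmomatic 0.36, FastQC 0.11.8, STAR 2.5.2, SAMtools 1.9 and DESeq2 1.22.2 with build mm10. The counting program, its annotation and its treatment of strand and multi-mapped reads are not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes can therefore be shared in ways that are not known.

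The deposited values are raw counts per Ensembl gene, with no normalization, for 49671 genes in each library. Total counts ran from 12594770 to 33710117 per library. Symbols and coordinates (mm10) came from the GENCODE annotation, which matched 49326 identifiers. The 345 others held 0.047% of counts and stayed in the tests. A count of 3, the limit that a count of 0 allows, corresponds to between 0.117 and 0.187 CPM (counts per megacount of the library) depending on the library. Within each group, all library pairs differed far beyond sampling noise (chi-square per degree of freedom from 17.5 to 75.1), so no pair looked like a second sequencing of the same library, and each was counted as a replicate, as titled. Repeated amplification of the same RNA could give such differences too, so they do not show that the pools were independent.

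From these counts, edgeR 4.0.16 in R 4.3.3 was run with TMM factors and filterByExpr, which kept 31961 genes. All 9 libraries were fitted in a group means model without covariates, sharing the estimate of spread, and the robust quasi-likelihood F test gave p-values with Benjamini-Hochberg adjustment within each of 3 comparisons at 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values are TMM scaled. Log2 CPM used a prior count of 2.

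The 25 gene lists and 12 cell type marker lists were fixed before the data were examined, as were the comparisons and most alternative settings. The gene lists covered immune checkpoint and immune evasion, JAK-STAT and PD-L1 regulators, MHC class I and class II presentation, interferon-stimulated genes, S phase, G2/M phase, quiescence and cell cycle arrest, pigment synthesis and melanosome, melanocyte and neural crest identity, WNT pathway targets, TGF-beta targets, glycolysis, cholesterol synthesis, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, senescence and secretory phenotype, NF-kB targets, immediate early genes, heat shock, unfolded protein response, p53 targets, antioxidant response, and lysosome and autophagy. The marker lists covered mast cells, macrophages and dendritic cells, T and NK cells, keratinocytes and hair follicle epithelium, fibroblasts, dermal papilla, endothelium, pericytes and smooth muscle, Schwann cells, adipocytes, skeletal muscle and erythroid cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists, with an estimated correlation and fry as alternatives.

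Genes named in the text followed a rule fixed before the data were examined. It took Cd274 and other checkpoint members, and the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 10 CPM, leaving out unnamed and most non-coding models. It also took up to 4 members per gene list with the smallest p, or the 2 most abundant where none passed, the most abundant marker per cell type, Nnt as a check on the colony, and Xist and Y-linked genes as a check on sex. Some genes that the rule takes are not reported here.

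Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), RLE factors, no filter, a stricter filter (at least 5 CPM in at least 2 libraries, 13639 genes), a test against a 1.5-fold change, a fit of only the compared groups, the replicate number as a block, and leaving out each library. Added after the data were seen were scaling factors from the genes of the stricter filter alone, the stricter filter for lists and for the relation of the comparisons, and the age comparison without marker genes. The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For adult McSC against melanoblasts (29664 genes run), edgeR recovered 17% of the 2-fold and 70% of the 4-fold genes, with 3 unchanged genes called. For aged against adult McSC (29421 genes run), it recovered 11% and 74%, with 6 unchanged genes called. DESeq2 called 30 and 40 unchanged genes in these runs of 31961 genes. The simulated genes varied independently, with the spread of the edgeR fit, and held no trend with abundance and no difference in background. Few genes were changed in them, so these rates need not carry over to the data.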

Results

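The study profiled melanocyte lineage cells from mouse skin at 3 ages, and its title names the checkpoint ligand PD-L1 in stem cell quiescence and aging. There were 3 libraries of newborn melanoblasts, 4 of adult McSC and 2 of aged McSC. Total counts were 23688288 to 33710117 in melanoblast, 19956424 to 21572026 in adult and 12594770 to 16362560 in aged libraries. Mitochondrial rRNA took between 21.5% and 37.6% of the counts of a library. In a principal component analysis of log2 CPM, the leading component held 56.7% of the variance and placed the 3 melanoblast libraries apart from the 6 McSC libraries. On it melanoblast replicate 3 lay at -88.01, adult replicate 2 at 1.13 and the other McSC libraries at 52.75 to 124.56. Adult replicate 2 had the lowest share of counts on the receptor genes described further on among McSC libraries. Melanoblast replicate 3 had the highest of its group, so this component need not reflect cell group alone. Melanoblast replicate 3 lay apart from all others on the next component (11.8%). Counts on Y-linked genes totalled 0 to 7 per library, which matched the stated sex.

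The comparison of adult McSC with melanoblasts asks what sets the resting stem cell apart from its dividing precursor. Adult McSC had much lower levels of cell division genes and lower levels of pigment genes. The camera call of the pigment list was lost with an estimated correlation (adjusted p = 0.219). By camera with its preset correlation, MHC class I, interferon-stimulated and immediate early genes were higher as lists, calls that were lost with an estimated correlation (adjusted p = 0.117, 0.133 and 0.133). Cd274, the gene of PD-L1, a ligand that restrains T cells, was 5.31-fold higher. It rose from 32.2 ± 4.73 CPM (SD, n = 3) in melanoblasts to 170.9 ± 18.3 CPM (SD, n = 4) in adult McSC, a log2 fold change of 2.41 (SE 0.226, adjusted p = 1.43e-08). Cd274 (ENSMUSG00000016496) is a protein-coding gene on chromosome 19, from 29367455 to 29388095 on the plus strand of mm10.

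**Figure D1:**
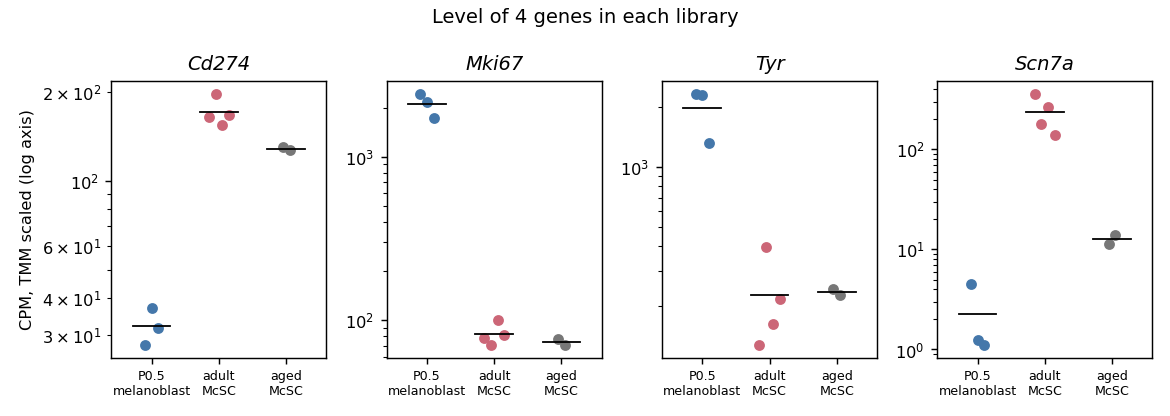
Level of Cd274, Mki67, Tyr and Scn7a in each library, in TMM-scaled CPM on a log axis. Each point is a library of 3 melanoblast, 4 adult and 2 aged libraries and each bar a group mean. The adult libraries sit between 154.5 and 197.2 CPM for Cd274, above the melanoblast libraries at 27.8 to 37.2 CPM.

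Among the 33 checkpoint and immune evasion genes, 13 rose and 4 fell, and 14 and 6 did so when adjusted over the list alone. The list was higher by camera (adjusted p = 0.0335; adjusted p = 0.327 with an estimated correlation), but not without melanoblast replicate 3 (adjusted p = 0.156). Lgals3, a galectin, rose from 7.10 to 185.6 CPM (log2 fold change 4.70, SE 0.276, adjusted p = 6.83e-12). Entpd1, an ectonucleotidase that degrades extracellular ATP, rose by 2.31 on the log2 scale (SE 0.315, adjusted p = 4.57e-06). Lgals9, another galectin, went the other way, from 152.5 to 13.1 CPM (log2 fold change -3.54, SE 0.28, adjusted p = 8.88e-10). Pdcd1lg2, the gene of PD-L2, was at 1.28 and 2.53 CPM and did not pass (adjusted p = 0.119), though it did with factors from abundant genes (adjusted p = 0.0309) and with limma voom (adjusted p = 0.0241). Of the 17 JAK-STAT and PD-L1 regulators, 4 rose and 6 fell, the same counts adjusted over the list alone, and with factors from abundant genes 8 rose and 4 fell. Their median was -0.12 (0.37 with these factors) and their mean 0.15, and camera did not call the list (adjusted p = 0.796). That median nevertheless lay at percentile 99.3 of random sets of equally abundant genes. Stat3, a transcription factor of cytokine signalling, rose by 1.53 and Socs3, which restrains that signalling, by 3.48 on the log2 scale (adjusted p = 1.25e-05 and 8.45e-10).

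Antigen presentation and interferon genes were mostly higher in adult McSC. Of 18 MHC class I genes, 12 rose and 4 fell, and 13 and 4 when adjusted over the list alone (median 2.08, camera adjusted p = 2.07e-11; adjusted p = 0.117 with an estimated correlation). H2-K1, a classical class I heavy chain, rose from 19.2 to 445.3 CPM, and Nlrc5, a transcriptional activator of class I genes, from 3.91 to 46.9 CPM. H2-Q6 rose by 7.02 on the log2 scale, a value that is uncertain because it shares sequence with neighbouring H2-Q genes. It also ran from 6.49 to 8.67 with a library left out. Of 8 class II genes, 6 rose, also when adjusted over the list alone (median 1.64, camera adjusted p = 0.00422; adjusted p = 0.303 with an estimated correlation). They were scarce, with Cd74, the invariant chain, at 12.7 and H2-Aa at 8.60 CPM in adult McSC. Of 27 interferon-stimulated genes, 14 rose and none fell, and 15 rose when adjusted over the list alone (median 1.30, camera adjusted p = 1.61e-08; adjusted p = 0.133 with an estimated correlation). Gbp2, a guanylate-binding protein, rose from 5.24 to 71.5 CPM and Ifit1 from 2.23 to 25.3 CPM. Keratinocyte and Schwann cell markers, described further on, were higher in the same libraries.

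Cell division genes fell. All 20 G2/M genes fell, also when adjusted over the list alone, with a median of -4.44 (camera adjusted p = 3.9e-87; adjusted p = 0.043 with an estimated correlation). Among the 37 lists, only this one was called with an estimated correlation in this comparison. Mki67, a proliferation marker, went from 2111 ± 351 CPM (SD, n = 3) to 82.6 ± 12.6 CPM (SD, n = 4), a log2 fold change of -4.67 (SE 0.246, adjusted p = 2.12e-12). Ube2c, Ccnb1 and Kif11, which act in mitosis, fell, with log2 fold changes of -5.22, -5.02 and -4.65. Of 19 S phase genes, 16 fell, also when adjusted over the list alone (median -1.51, camera adjusted p = 4.81e-14; adjusted p = 0.133 with an estimated correlation). Mcm2 and Mcm5, subunits of the replicative helicase, fell, with log2 fold changes of -2.68 and -2.69. Of 21 quiescence and arrest genes, 9 rose and 4 fell, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.0112; adjusted p = 0.543 with an estimated correlation and 0.171 without melanoblast replicate 3). Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 2.66, Btg2, an antiproliferative gene, by 2.93, and Pdk4, a kinase that restrains pyruvate oxidation, by 4.41 on the log2 scale.

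Pigment and lineage genes also fell. Of 18 pigment genes, 15 fell, also when adjusted over the list alone (median -1.85, camera adjusted p = 7.92e-17; adjusted p = 0.219 with an estimated correlation). Tyr, the rate-limiting enzyme of melanin synthesis, went from 1988 ± 580 to 226.4 ± 121 CPM (SD, n = 3 and 4), and Oca2 and Slc24a5, melanosomal transport genes, fell, with log2 fold changes of -3.94 and -3.64. Of 15 identity genes, 11 fell, and 12 when adjusted over the list alone (median -1.28, camera adjusted p = 3.83e-07; adjusted p = 0.303 with an estimated correlation). Sox10, a transcription factor of the lineage, remained at 224.8 CPM from 593.5 CPM, and Ednrb, the endothelin receptor, at 362.3 from 1538 CPM. Of 12 WNT targets, 3 rose and 6 fell, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0594).

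Immediate early genes, which respond within minutes to stimuli that include tissue dissociation, were higher. Of 17, 16 rose, also when adjusted over the list alone (median 2.16, camera adjusted p = 7.92e-17; adjusted p = 0.133 with an estimated correlation). Egr1 went from 159.7 to 1430 CPM and Fosb from 153.5 to 1091 CPM. Of 12 heat shock genes, 6 rose and 2 fell, and 6 and 3 when adjusted over the list alone (median 0.61, camera adjusted p = 0.00905; adjusted p = 0.489 with an estimated correlation). Hspb1, a small chaperone, rose by 4.62 on the log2 scale, and Hspa1a by 5.63, which is uncertain because its reads can be shared with its near-identical neighbour Hspa1b. Of 17 NF-kB targets, 8 rose and 1 fell, and 11 and 1 when adjusted over the list alone (adjusted p = 0.0052; adjusted p = 0.457 with an estimated correlation). Of 12 TGF-beta targets, 6 rose, and 8 when adjusted over the list alone (adjusted p = 0.00137; adjusted p = 0.133 with an estimated correlation), with Ccn2, a matricellular protein, up by 3.96 on the log2 scale. Of 22 senescence and secretory genes, 7 rose and 1 fell, and 8 and 1 when adjusted over the list alone (adjusted p = 0.00671; adjusted p = 0.303 with an estimated correlation). Without melanoblast replicate 3 camera did not call the heat shock, NF-kB and senescence lists (adjusted p = 0.226, 0.103 and 0.0667). Keratinocyte markers rose in the same libraries.

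Genes of translation and energy metabolism were lower. Of 81 ribosomal protein genes, 74 fell, and 76 fell and 1 rose when adjusted over the list alone (median -1.13, camera adjusted p = 2.84e-21; adjusted p = 0.327 with an estimated correlation). Of 80 nuclear-encoded oxidative phosphorylation genes, 64 fell, and 66 fell and 1 rose when adjusted over the list alone (median -1.21, adjusted p = 1.93e-19; adjusted p = 0.303 with an estimated correlation). Rps24 and Atp5g3 fell, with log2 fold changes of -1.54 and -1.61. Of 11 mitochondrially encoded genes, 8 fell, and 10 when adjusted over the list alone (adjusted p = 9.05e-07; adjusted p = 0.303 with an estimated correlation), mt-Cytb from 12610 to 4334 CPM. Of 18 glycolysis genes, 9 fell and 2 rose, and 10 and 4 when adjusted over the list alone (adjusted p = 0.000952; adjusted p = 0.374 with an estimated correlation). Ldha and Gapdh fell, with log2 fold changes of -2.02 and -2.15. Of 17 lysosome and autophagy genes, 11 fell, and 13 when adjusted over the list alone (adjusted p = 7.92e-06; adjusted p = 0.374 with an estimated correlation), and of 15 antioxidant genes 7 fell and 3 rose, also when adjusted over the list alone (adjusted p = 0.0461; adjusted p = 0.56 with an estimated correlation). Camera did not call cholesterol synthesis (5 of 19 fell, median -0.34, or 0.13 with factors from abundant genes), the unfolded protein response (1 rose and 4 fell of 14, median 0.36, mean 0.01) or p53 targets (3 rose and 4 fell of 17). Adjusted over the list alone these counts were 5 fallen for cholesterol synthesis, 4 and 4 for the unfolded protein response, and 3 and 4 for p53 targets. With factors from abundant genes these splits turned, to 3 risen and 2 fallen for cholesterol synthesis, 6 and 3 for the unfolded protein response, and 5 and 2 for p53 targets. The falls of ribosomal, oxidative phosphorylation and lysosome genes were then 53, 45 and 5, with medians of -0.63, -0.70 and -0.27. These lists hold abundant genes, whose median over all 4393 genes above a log2 CPM of 5 was -0.83. Against random sets of equally abundant genes, the medians of glycolysis, lysosome and antioxidant genes lay at percentiles 16, 49.6 and 50.7, and with the stricter filter camera called none of the 3 (adjusted p = 0.153, 0.0578 and 0.714). The antioxidant call was lost in 11 of 15 settings, among them the fits without melanoblast replicate 1 or 2 (adjusted p = 0.0652 and 0.151) or adult replicate 1, 3 or 4 (adjusted p = 0.0777, 0.0501 and 0.0675).

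Markers of other skin cells differed as well. Of 15 keratinocyte and hair follicle markers, 14 rose, and 14 rose and 1 fell when adjusted over the list alone (median 2.63, camera adjusted p = 1.81e-14; adjusted p = 0.133 with an estimated correlation), with Dsp, a desmosome gene, going from 50.7 to 386.2 CPM. Of 9 Schwann cell markers, 4 rose, and 7 when adjusted over the list alone (median 1.33, adjusted p = 9.06e-07; adjusted p = 0.133 with an estimated correlation). Camera called none of the 10 other marker lists. Fibroblast markers split, with 2 risen and 5 fallen of 10, or 2 and 1 with factors from abundant genes, and Col3a1, a fibrillar collagen, went from 590.2 ± 377 to 170 ± 60.0 CPM (SD, n = 3 and 4). Macrophage and dendritic cell markers rose in 4 of 13 and endothelial markers in 5 of 11. Smaller counts passed for dermal papilla (2 of 7 rose), T and NK cells (1 of 10 rose), skeletal muscle (2 of 7 rose), pericytes and smooth muscle (2 of 8 fell), adipocytes (2 of 8 fell) and mast cells (2 of 10 fell), and for 0 of 6 erythroid markers. The rises of T and NK cell and skeletal muscle markers stayed within the level of the receptor genes described further on, and 3 of the 4 macrophage rises exceeded it. The most abundant mast cell marker, Cpa3, went from 12.9 to 2.10 CPM, and Cd68 of macrophages was at 18.4 and 24.4 CPM (adjusted p = 0.243; adjusted p = 0.0278 with factors from abundant genes, 0.0299 with the stricter filter and 0.0215 without melanoblast replicate 3).

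The largest rises included Akr1c18, a steroid-metabolizing reductase (log2 fold change 7.02), Scn7a, a sodium channel gene among the Schwann cell markers (6.72), Fgl2 (6.00), Fcgr2b, an inhibitory Fc receptor (5.86), Kcna1, a potassium channel (5.63), and Anxa8 (5.57). Tgtp1 and Tgtp2, interferon-inducible GTPases, rose to 10.7 and 14.7 CPM from under 0.3 CPM, though their reads can be shared between these near-identical genes. The largest falls included H19, an imprinted non-coding RNA, from 19.2 to 0.214 CPM, and Sox11, a transcription factor (log2 fold change -4.97). In all, 10676 of 31961 genes changed, 4836 up and 5840 down, and 8333 of them by at least 2-fold. The split turned without melanoblast replicate 3 (7400 up and 6659 down), with DESeq2 (6316 and 5857), with limma voom (7550 and 7263), without a filter (6630 and 4867) and with the stricter filter (3531 and 3346). Scaling on abundant genes alone shifted the median of all genes from 0.39 to 0.86 and the split to 7960 up and 3312 down, so directions of small changes depend on the scaling. The medians of the 37 lists moved up by 0.46 to 0.552 with it. Counts were also taken on 1427 olfactory and vomeronasal receptor genes, most of which skin is not known to use. They averaged 1086 ± 274 ppm (SD, n = 4) in adult and 252.3 ± 96.5 ppm (SD, n = 3) in melanoblast libraries. Here ppm are counts scaled as for CPM but to the full library total. Of the 969 receptor genes tested, 270 rose and 1 fell. Of the 4836 rises, 2237 reached an adult level no higher than the 95th percentile of these receptor genes (1.94 CPM), and of the 5840 falls 10 started from a melanoblast level no higher than that percentile there (0.859 CPM).

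**Figure D2:**
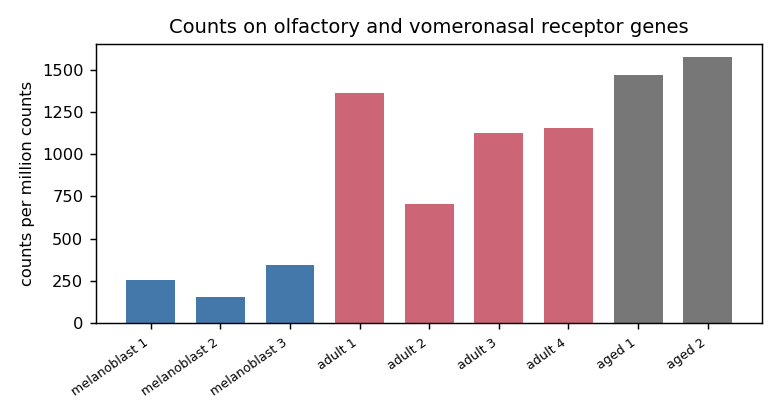
Counts on olfactory and vomeronasal receptor genes in ppm of all counts, with a bar for each library, blue for melanoblast, red for adult and grey for aged. The melanoblast libraries lie between 154.5 and 347.4, the adult libraries between 705.7 and 1359 and the aged libraries at 1467 and 1573.

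The comparison of aged with adult McSC asks what differs in the resting stem cell late in life. Few genes passed with edgeR, and most of these were lower in aged McSC. Schwann cell markers were lower, and levels of cell cycle, pigment and identity genes did not pass the test gene by gene. Cd274 was at 128.5 ± 1.61 CPM (SD, n = 2) against 170.9 ± 18.3 CPM (SD, n = 4), a log2 fold change of -0.41 (SE 0.239, adjusted p = 0.557) that was not distinguishable from the spread between pools. In all, 97 genes changed, 17 up and 80 down, all by at least 2-fold, and 3275 had an unadjusted p under 0.05. With factors from abundant genes the count was 61, 23 up and 38 down. The split turned with limma voom (850 up and 670 down) and without aged replicate 1 (77 up and 46 down).

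Of the 9 Schwann cell markers, 6 fell, and 7 when adjusted over the list alone (median -1.30, camera adjusted p = 1.05e-15; adjusted p = 0.0341 with an estimated correlation). Of the 37 lists, only this one was called with an estimated correlation for age. Scn7a went from 236.2 ± 98.6 to 12.7 ± 1.88 CPM (SD, n = 4 and 2), a log2 fold change of -4.22 (SE 0.518, adjusted p = 0.000432). Pmp22, a myelin protein, had a log2 fold change of -1.27 (adjusted p = 0.0454). Other genes with large falls were the potassium channels Kcna1 and Kcna6 (log2 fold changes of -4.21 and -3.58), the neurotrophic factor receptor Gfra3 (-3.18), the adhesion gene Cadm2 (-3.42), Fcgr2b (-3.91), Gatm (-3.70), Olfml2b (-3.49) and Fgl2 (-3.33). Of 10 fibroblast markers, 3 fell, also when adjusted over the list alone (median -0.77, camera adjusted p = 1.81e-06; adjusted p = 0.486 with an estimated correlation), Col3a1 among them at 23.02 CPM in aged McSC. With factors from abundant genes 0 fibroblast and 4 Schwann cell markers fell. Of the 11 endothelial markers 0 passed, and 4 fell when adjusted over the list alone (median -1.01, camera adjusted p = 0.000363; adjusted p = 0.562 with an estimated correlation). Of 15 keratinocyte markers, 1 fell, and 3 fell and 2 rose when adjusted over the list alone (adjusted p = 0.00759; adjusted p = 0.562 with an estimated correlation), and Dsp was at 268.6 CPM (adjusted p = 0.614). The keratinocyte call was lost without adult replicate 3 (adjusted p = 0.0914) or aged replicate 2 (adjusted p = 0.0764).

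Among checkpoint genes 2 of 33 fell, and 3 when adjusted over the list alone. Entpd1 went from 23.6 to 5.33 CPM (log2 fold change -2.14, SE 0.365, adjusted p = 0.00482) and Cd200, a ligand that restrains myeloid cells, from 76.3 to 28.2 CPM (log2 fold change -1.44, SE 0.282, adjusted p = 0.0188). Lgals3 was at 101.8 CPM (adjusted p = 0.25). Camera placed the list lower (adjusted p = 0.0338; adjusted p = 0.486 with an estimated correlation), with a median of -0.05 that became 0.16 with factors from abundant genes. That call was lost without adult replicate 1 (adjusted p = 0.0661) or aged replicate 2 (adjusted p = 0.213). The list median lay at percentile 54.3 of random sets of equally abundant genes, so it did not stand out from genes of its abundance. The falls of Entpd1 and Cd200 stood beside the lower Schwann cell markers in the same libraries.

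The largest rises were Atp6v0d2, a proton pump subunit, from 11.5 ± 1.08 to 133 ± 30.9 CPM (SD, n = 4 and 2; log2 fold change 3.53, SE 0.333, adjusted p = 4.7e-06) and Trim9, a ubiquitin ligase, from 3.89 to 34.4 CPM (log2 fold change 3.14, SE 0.299, adjusted p = 4.7e-06). Ctnnd2 rose by 2.44, Mybpc1 by 1.93 and Slc10a1 by 1.63 on the log2 scale. Nexn and Nabp1 rose by 2.18 and 1.70, but both rest on aged replicate 2, without which the values were 0.28 and 0.80 (adjusted p = 0.956 for each). Tgfbi, Igfbp3 and Igfbp7 fell, with log2 fold changes of -1.33, -1.55 and -2.82. Over 14 other settings, Nexn and Tgfbi passed in 6, Igfbp3 and Slc10a1 in 7 and Igfbp7 in 10. Ctnnd2 passed in 11, Nabp1 in 12 and Mybpc1 in 13 of them, and Atp6v0d2 and Trim9 in all. Of 12 TGF-beta targets 1 rose and 1 fell, and 1 rose and 2 fell when adjusted over the list alone. Of 22 senescence and secretory genes 1 rose and 2 fell, also when adjusted over the list alone.

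Several lists shifted without single genes passing. The 81 ribosomal protein genes had a median of -0.90 with 0 past the threshold over all genes and 72 lower when adjusted over the list alone (camera adjusted p = 4.68e-51; adjusted p = 0.481 with an estimated correlation), with Rpl4 at 747.8 and 456.1 CPM. DESeq2 and voom counts for the whole comparison were 314 and 1520 genes. The camera call was also lower for oxidative phosphorylation (median -0.56, adjusted p = 2.39e-14; adjusted p = 0.486 with an estimated correlation), interferon-stimulated genes (median -0.56, adjusted p = 5.29e-07; adjusted p = 0.481 with an estimated correlation) and JAK-STAT regulators (median -0.44, adjusted p = 1.32e-05; adjusted p = 0.486 with an estimated correlation). Adjusted over the list alone, 2, 6 and 3 of their genes were lower. With factors from abundant genes the medians of these 3 lists were -0.34, -0.35 and -0.23, and those of identity genes and NF-kB targets, below, -0.21 and -0.16. Ifitm3, an interferon-induced membrane protein, was at 93.3 and 34.2 CPM (adjusted p = 0.0711) and passed in 6 of 14 other settings, among them DESeq2 (adjusted p = 0.0101) and the fit without aged replicate 1 (adjusted p = 0.0479). Identity genes (median -0.44, adjusted p = 0.00015), lysosome genes (-0.33, 0.000898), MHC class I (-0.24, 0.0115), NF-kB targets (-0.35, 0.0115) and glycolysis (-0.28, 0.0414) were lower by camera, with adjusted p = 0.562, 0.562, 0.486, 0.562 and 0.562 with an estimated correlation. With the stricter filter camera called none of these 5 (adjusted p = 0.0759, 0.213, 0.494, 0.197 and 0.739). The median of all abundant genes was -0.34. The lysosome, MHC class I and glycolysis medians lay at percentiles 44.2, 56.6 and 44 of random sets of equally abundant genes, so these 3 shifts did not stand out. The JAK-STAT, identity and NF-kB medians lay at percentiles 6.2, 7.5 and 6.9. Those of ribosomal, oxidative phosphorylation and interferon-stimulated genes lay at percentile 0. Without aged replicate 2 the lysosome, MHC class I, NF-kB and glycolysis calls were lost (adjusted p = 0.0672, 0.213, 0.162 and 0.825), as were NF-kB without adult replicate 1 (0.0539) and glycolysis without adult replicate 2 or 3 (0.239 and 0.0552). Only MHC class II was called higher (median 0.76, adjusted p = 0.0338; adjusted p = 0.562 with an estimated correlation), and without aged replicate 1 its direction turned (adjusted p = 0.962). That call was also lost without adult replicate 1 or 4 (adjusted p = 0.0628 and 0.0575). Cd74 was at 20.1 ± 15.4 and H2-Aa at 12.3 ± 10.5 CPM (SD, n = 2) in aged McSC. Camera did not call G2/M phase (adjusted p = 0.963), S phase (0.412), pigment synthesis (0.448, but higher with the stricter filter at 0.00892), quiescence genes (0.247) or immediate early genes (0.963). Mki67 was at 73.9 CPM, Dct, a melanin synthesis enzyme, at 4349 CPM and Kit at 790.3 CPM in aged McSC, with adjusted p = 0.86, 0.652 and 0.751. In the same libraries the Schwann cell, fibroblast, endothelial and keratinocyte marker lists had medians of -1.30, -0.77, -1.01 and -0.52.

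**Figure D3:**
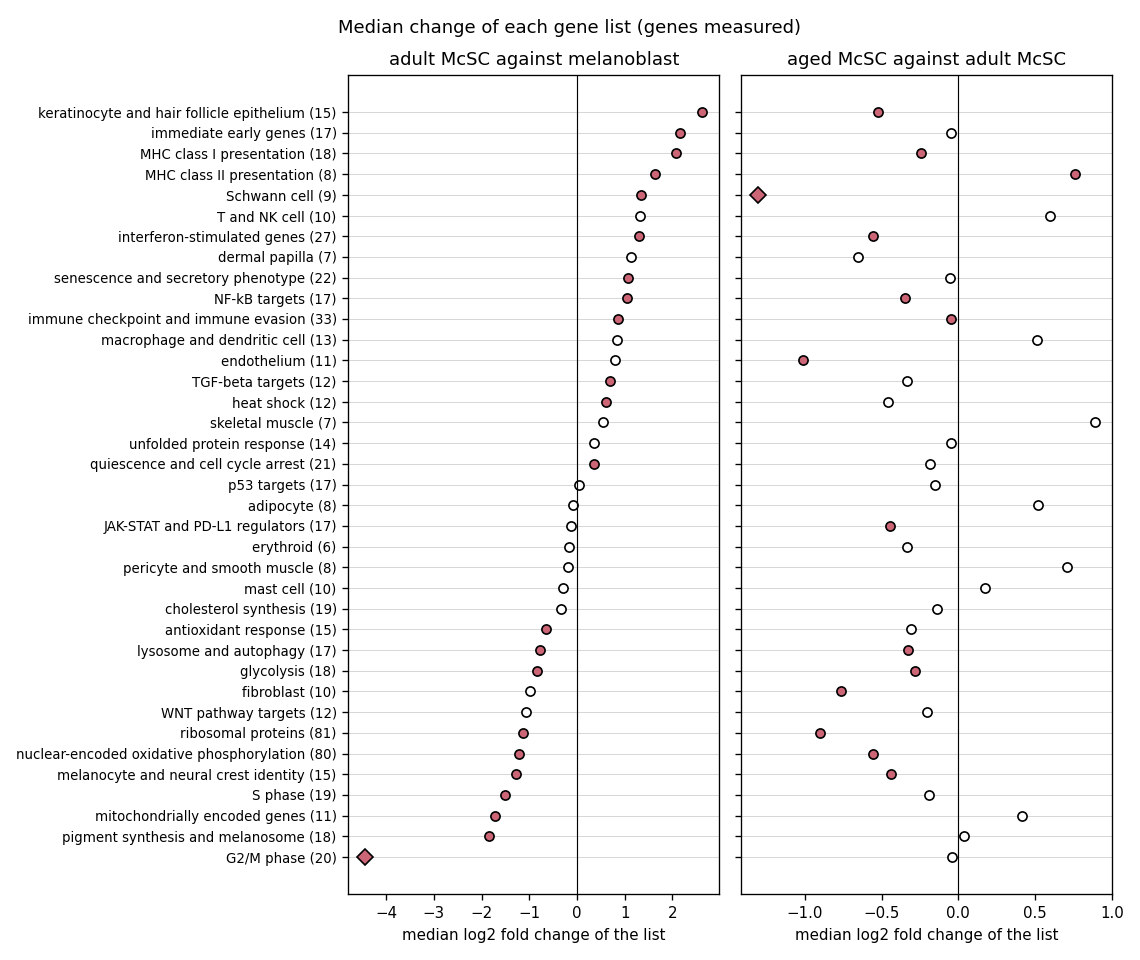
Median log2 fold change of each gene list and cell type marker list in both comparisons, with the number of genes measured in brackets. Filled symbols were called by camera and diamonds also with an estimated correlation, which were G2/M phase for adult McSC against melanoblasts (median -4.44) and Schwann cell markers for aged against adult McSC (median -1.30).

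Aged McSC stood in few libraries, and leaving out aged replicate 2, adult replicate 1 or adult replicate 3 left 13, 46 and 49 genes in place of 97. Among the named genes, calls that held under all settings run for single genes were those of Cadm2, Olfml2b, Atp6v0d2 and Trim9. Nnt, which C57BL/6J carries as a partial deletion, was at 24.1 ± 5.74, 14.5 ± 1.95 and 11.2 ± 1.43 CPM (SD) in melanoblast, adult and aged libraries, with adjusted p = 0.652 between the last 2 groups.

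The remaining comparison, aged McSC against melanoblasts, gave 13005 genes, 6514 up and 6491 down, and 11365 up and 3448 down with factors from abundant genes. Without aged replicate 1 the count was 7410, and without aged replicate 2 it was 8440. Of these rises 3752 and of these falls 5278 were shared with adult McSC against melanoblasts, against 985.6 and 1186.1 for independent lists. The melanoblast libraries are common to both comparisons, and across genes their differences of mean log2 CPM correlated at r = 0.89 against 0.489 in 100 simulations of unchanged groups (covariance 1.57 against 0.166). Genes are not independent replicates.

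The change with age was then set against the change from melanoblast to adult. These share the adult libraries with opposite sign, so simulated unchanged groups gave r = -0.367 across genes (covariance -0.117). The observed correlation was 0.162 (covariance 0.132), and 0.224 with the adult libraries split 2 and 2 between the comparisons. The simulated groups held no trend with abundance. In the data, abundant genes lay below all genes in both comparisons (gaps between medians of -1.22 and -0.414). A trend that both comparisons share can itself give a positive correlation, and its part was not tested. Among called genes the direction was mostly opposite. Of the 80 genes lower with age, 51 had risen from melanoblast to adult McSC, against 12.1 for independent lists, and 10 had fallen, against 14.6. Scn7a, Kcna1, Fgl2 and Fcgr2b were among the 51. Chance values of the shared adult libraries can add to this overlap.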

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

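Xist, the RNA that silences an X chromosome in female cells, was at 2203 CPM in adult McSC replicate 2, apart from the other adult libraries at 1839 to 1896 CPM. The gap made up 0.844 of the range of the 4 adult libraries. It was the only 1 of 79 named genes screened that passed the criterion for a library far from the others, and no explanation was tested. A screen of this many genes can flag a gene by chance.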

How the results depend on the processing

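Scaling on abundant genes, the stricter filter for lists and for the relation, and the fit without marker genes were chosen after the data were seen. For adult McSC against melanoblasts, 51 of the 52 called named genes kept their call in every setting run for single genes, the exception being Nnt. The test against a 1.5-fold change was run for counts only. The count of 10676 became 6877 with the stricter filter, which tests fewer genes, and 6238 when testing for a change above 1.5-fold, and lay between 8056 and 14059 with a library left out. For aged against adult McSC, the count of 97 was 314 with DESeq2, 343 without a filter, 1520 with limma voom (850 up), 311 with only the compared groups fitted, 36 for a change above 1.5-fold, and 61 with factors from abundant genes. It ran from 13 (without aged replicate 2) to 123 (without aged replicate 1, 77 up) with a library left out, and was 87 without marker genes. The cause was not tested beyond the construction of each setting. All 97 genes were also called by DESeq2 and without a filter, 94 by voom, 58 with the stricter filter and 51 with factors from abundant genes. No setting called a gene in the opposite direction. Of the 25 called named genes, 21 lost their call in at least 1 fit without a library, and 9 with factors from abundant genes. Voom also called 5 named genes with age that did not pass with edgeR, Lgals3 and Rpl4 among them. For aged McSC against melanoblasts, the 13005 genes became 7611 with the stricter filter and 7410 to 16292 with a library left out.

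Replicate numbers gave no clear sign of pairing, though so few pairs cannot exclude it. Deviations of same-numbered melanoblast and adult libraries correlated at -0.189, 0.339 and -0.096, and those of adult and aged libraries at 0.01 and 0.111. The differently numbered pair of melanoblast replicate 3 and adult replicate 1 reached 0.474. With the replicate block, the age comparison gave 172 genes.

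Of the 22 lists called for adult McSC against melanoblasts, 1 stayed with an estimated correlation, and 19 to 24 lists were called with a library left out. Without melanoblast replicate 3 the 12 higher lists became 7. Of the 15 called with age, 1 stayed with an estimated correlation, 1 with fry and 6 with the stricter filter, which called 7 in all, and 13 to 18 lists were called with a library left out. With a library left out, the adjusted p ran from 1.12e-05 to 0.962 for MHC class II presentation with age, which turned lower without aged replicate 1, and from 8.95e-06 to 0.817 for mitochondrially encoded genes, which turned lower without aged replicate 2 (adjusted p = 0.00124). The correlation of the age change with the melanoblast-to-adult change stayed positive and above its simulated range throughout, at 0.085 without a filter, 0.17 with the stricter filter and 0.067 to 0.249 with a library left out. The simulations held no trend with abundance, so they do not show what a shared trend would give. A fit that leaves 1 aged library assumes that it varies like the other groups.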

Other observations

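Of the tests here, those on the imprinted and GTPase lists, on Schwann cell numbers and other cell types, and all those on Cd274 were chosen after the result was seen. The p-values of the imprinted and GTPase lists were adjusted in each comparison over these 2 lists alone. Their adjusted values are therefore not on one scale with those of the lists fixed before the data were examined. Related interferon-inducible GTPases, which act against intracellular pathogens, were also higher in adult McSC. Of 14 measured besides Tgtp1 and Tgtp2, 4 immunity-related GTPases and 10 guanylate-binding proteins, 13 rose, with a median of 3.01 (camera adjusted p = 5.29e-16; adjusted p = 0.00362 with an estimated correlation). Gbp2 and Gbp3 among them are also in the interferon-stimulated list, so the lists are not separate evidence. With age their median was -0.54 and 0 passed the test (camera adjusted p = 0.00041; adjusted p = 0.105 with an estimated correlation). Imprinted growth genes went mostly the other way. Without H19, 8 of 13 fell and 2 rose, with a median of -0.96, or -0.444 with factors from abundant genes (camera adjusted p = 0.000156; adjusted p = 0.0854 with an estimated correlation). Igf2, a fetal growth factor, and Grb10, a growth-restraining adaptor, both chosen after their values were seen, fell by 4.19 and 3.19 on the log2 scale.

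In adult libraries abundant genes were lower and scarce genes higher, with a gap of -1.22 between the median log2 changes of abundant and of all genes. Removing the 2 mitochondrial rRNA genes left a gap of -1.17. Such a removal rescales each library and moves all genes alike, so this test could hardly change the gap. For the same reason, a share of counts taken by these genes does not by itself give such a gap. Scaling on abundant genes likewise moved both medians, to -0.342 for abundant and 0.865 for all genes. Background reads from genomic DNA or unspliced RNA may contribute, since the share of counts on olfactory and vomeronasal receptor genes in adult libraries was on average 4.3 times that in melanoblast libraries, and each adult library lay above each melanoblast library. The same share could also rise if a resting cell holds less RNA, which was not tested, and the age of the mice remains open. Scarce genes that rose are therefore less certain than abundant ones.

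Schwann cell genes were lower in aged McSC. Scaling alone is argued against, as the list median stayed at or below -0.98 under 7 settings of scaling and filter, some of which scale alike. A lower share of every other cell type cannot be told apart. Keratinocyte, fibroblast and endothelial markers were also lower by camera, though these calls were lost with an estimated correlation (adjusted p = 0.562, 0.486 and 0.562). Pericyte and smooth muscle markers had a median of 0.71 (SE 0.264 over member genes, not between libraries) without being called higher (camera adjusted p = 0.247). That comparison took lists with at least 3 members over 5 CPM. Among the scarcer lists, macrophage, T and NK cell and skeletal muscle markers had medians of 0.51 (SE 0.154), 0.598 (SE 0.187) and 0.893 (SE 0.169). Those of adipocyte and mast cell markers were 0.518 (SE 0.274) and 0.176 (SE 0.268). Dermal papilla and erythroid markers went the other way, at -0.651 (SE 0.244) and -0.332 (SE 0.505). These SE are again over member genes. Camera called none of these lists (adjusted p = 0.0511, 0.108, 0.0797, 0.146, 0.717, 0.306 and 0.717 in the order given). In aged libraries T and NK cell and skeletal muscle markers averaged 2.065 and 1.986 CPM, below the 95th percentile of receptor genes (2.37 CPM). Fewer Schwann cells in the aged sorts cannot be told apart either. The sort would remove cells without KIT. Over the 4 adult libraries the 80 genes lower with age had a mean pairwise correlation of 0.498, above the 95th percentile of 0.363 of 1000 matched random sets, but any factor shared within pools would give this. The 70 of them outside the marker lists correlated on average at 0.15 with the Schwann cell list, below the 0.509 with endothelial markers and the 0.509 with pericyte and smooth muscle markers. A change within the cells, the other colony and age itself stay open and untested.

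Cd274 was higher in adult McSC at 2.40 or more on the log2 scale under 7 settings of scaling and filter, some of which scale alike. This argues against the choice among these settings as the cause. All of them scale relative to the library, so they cannot show a change in the RNA held per cell. Within groups over the 6 McSC libraries, log2 Cd274 had a slope of -0.334 (SE 0.132) on the keratinocyte markers and -0.289 (SE 0.17) on the Schwann cell markers. Either cell type as the whole source would need a slope near 1, which these slopes did not reach. Between groups, however, the keratinocyte markers changed much as Cd274 did. Their mean log2 change was 2.54 in adult McSC against melanoblasts and -0.445 with age, beside 2.41 and -0.411 for Cd274. With age Cd274 differed from the Schwann cell median of -1.30 by 0.891 (SE 0.709, partly a spread over markers), which is not clear. Neither cell type can therefore be told apart as a source. The highest slope over the marker lists with at least 3 members over 5 CPM was 0.097 (SE 0.148), for fibroblasts. Macrophages and dendritic cells cannot be told apart, since their slope of -0.12 (SE 0.245) rests on a list with only 2 members over 5 CPM. The sort would remove CD45-positive immune cells and cells without KIT. A rise in the stem cells themselves and the age of the mice stay open, as hypotheses. So does RNA from keratinocytes, Schwann cells, macrophages, dendritic cells or, in smaller part, other cells.

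For adult McSC against melanoblasts, only 1 of the 35 splits of the 7 libraries, the real one, gave as many genes (9773 in a fit of these groups, highest other 2404), so a chance division of the libraries is excluded at 0.05. For aged against adult McSC there are only 15 splits, too few for a share under 0.05, with 311 genes in the real 1 and 6 in the highest other.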
